A study of Arabidopsis thaliana with 22 samples.

How the data were processed

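RNA was measured by sequencing in 22 libraries of etiolated Arabidopsis thaliana Col-0 seedlings, 2 per group in 11 groups. Per the labels' protocols, seeds were plated on medium with 2% sucrose, stratified, induced to germinate in white light and grown for 6 days in darkness at about 20 °C. Seedlings were then exposed to blue, red or white light, sampled at 0 h, or kept dark for 6 h. Libraries were made from 4 µg of total RNA with an Illumina TruSeq kit, and the labels give 4 libraries per pool for dark samples and 2 for light samples. The deposited table gives, per the file headers, a raw read count for each gene in each library, and the values are whole numbers with no normalisation. The genome build is TAIR 10, per the submitters' processing notes. The aligner, the counting tool, the strand setting and the treatment of reads with several positions are not given in the sources used here. Counts of near-identical copies (LHCB1 and LHCB2 genes, Rubisco small subunit genes, neighbouring SAUR genes, seed storage genes) are therefore uncertain, as are counts of overlapping genes. White light for 1 h was not analysed here.

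The table holds 33602 genes. Gene names came from the TAIR10.1 RefSeq table by locus tag, which matched 32835 of them and left 767 without a match, and no coordinates were used. Total counts per library lay between 35000731 and 138804638. Genes were filtered with filterByExpr (minimum count 10) on the groups, which kept 23011 genes holding 99.99% of counts. The main test was the edgeR 4.0.16 quasi-likelihood F test in R 4.3.3, with TMM factors, 1 mean per group over all 22 libraries and 11 residual degrees of freedom. P values were adjusted by Benjamini-Hochberg over the genes kept, and a gene was called at an adjusted p under 0.05. Fold changes are given on the log2 scale with standard errors.

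Comparisons were each light group against the dark group of its own series (0 h for 1 h, 6 h dark for 6 h), the mean over the 3 colours at 6 h, the mean of 6 h dark against 0 h, the differences between colours and between times as interaction contrasts, and the 0 h libraries between series. The text names genes from a set fixed by rule, but not every gene of it. The set held the 5 genes with the largest and the 5 with the smallest change in each comparison. These were taken among called genes with at least 10 CPM and no overlap between the groups' libraries. It also held the called members of each list with the smallest adjusted p (2 or 4 per list), and 12 genes chosen in advance. For interactions the rule took the 5 largest and 5 smallest without the overlap condition, and of these the text names those whose call held without each library in turn, a limit chosen after their values were seen. Levels are CPM, counts scaled to the normalised library size, with the SD of 2 libraries.

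The 22 gene lists hold 419 genes, of which 415 were measured. They cover photosystem and light-harvesting proteins, Calvin cycle, chlorophyll, carotenoid and flavonoid synthesis, photoreceptors, light signalling, the clock, auxin, gibberellin and brassinosteroid, the cell wall, SR and other splicing factors, sugar starvation, photorespiration, seed reserve mobilisation, DNA replication, heat shock, touch and oxidative stress, and markers of seed storage, root and guard cells. Lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01, adjusted over the lists of a comparison, and again with the correlation between genes estimated. At 6 h no list of the mean contrast held at an adjusted p under 0.05 with an estimated correlation, and at 1 h the light signalling and clock lists did. The share of counts from plastid and mitochondrial genes was compared with an exact permutation test within series.

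The models, the tests of the comparisons, the lists, the rule for named genes and the alternatives in the next sentence were chosen before the data were examined. Alternatives were RLE factors, library totals alone, no filter or a stricter one (5 CPM in 2 libraries), a log2 change of at least 1, DESeq2 1.42.0, no organelle genes, the replicate number as a block, only the libraries of the contrast, and each library left out in turn. Where a left-out library left a group with 1 library, the fit assumed that it varied like the other groups. Chosen after the data were seen were thinning to the smallest total, leaving out the blue libraries numbered 1, and comparing 6 h with 1 h of light directly, and also the tests of depth, pool size, levels in darkness and replicate 2 of white light as explanations. Libraries with the same number within a series deviated together from their group means, with correlations of 0.0478 to 0.574 (median 0.287) and 14 of 15 over 0.1. Between series 30 of 40 were over 0.1, with a median of 0.189. Blocked values are therefore given beside the comparisons between colours at 6 h.

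The tests were checked on simulated counts with 200 genes changed in each comparison, drawn at each gene's share of all counts, its dispersion and the library totals. For blue light at 1 h, over 22804 genes, edgeR recovered 13.4% of genes changed 1.5-fold, 52.2% of those changed 2-fold and 78.8% of those changed 4-fold, with 5 false calls. For the mean at 6 h, over 22814 genes, the shares were 72.7%, 82.1% and 98.5%, with 5 false calls. For the difference between red and white light, over 22794 genes, they were 6.06%, 28.8% and 75.4%, with 4 false calls. Simulated counts with no change gave 0 calls in each contrast. In the real data these 3 comparisons called 1870, 13441 and 627 genes, so the simulation changed fewer genes. Simulated libraries were also drawn independently, while real libraries with the same number deviated together. Recovery and false calls in the real comparisons may therefore differ from these values. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.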

Results

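Gene counts were analysed for 22 libraries from seedlings of Arabidopsis thaliana Col-0 that had grown for 6 days in darkness. Seedlings were then placed in continuous blue or red light for 1 or 6 h, or in white light for 6 h. Each colour had dark controls of its own, sampled at 0 h and after 6 h more of darkness. The 11 groups held 2 libraries each, and the labels do not say whether the replicates of a group were separate cultures. Total counts lay between 35000731 and 72685876 in the 12 dark libraries and between 59054903 and 138804638 in the 10 light libraries. All dark libraries were sequenced 4 per pool and all light libraries 2 per pool. The first principal component, with 52.6% of the variance, ran from the dark libraries through 1 h to 6 h of light. The second, with 9.84%, was highest in the blue series libraries numbered 1. In every group of all 3 series the library numbered 1 lay above that numbered 2 on it. All fold changes below compare light with the dark libraries of the same series.

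**Figure D1:**
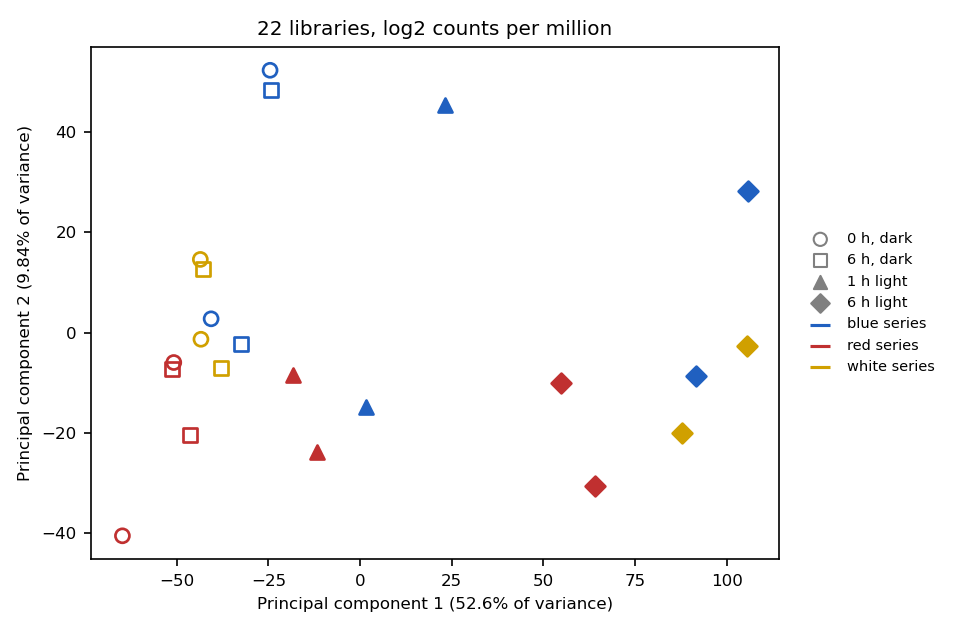
Principal components of log2 CPM in the 22 libraries, 1 point per library, with colour for the light series and shape for the time point. Dark libraries lie together at one end of the first component (52.6% of the variance) and 6 h light libraries at the other.

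The first hour of blue light was compared with the blue series at 0 h to see which transcripts respond early. Most of the light signalling and clock genes measured rose within that hour, and 9 of 30 auxin response genes fell. GA2OX1 (AT1G78440), which inactivates gibberellin, rose 92.3-fold, with a log2 change of 6.53 (SE 0.27, adjusted p = 1.05e-08). SIG5 (AT5G24120), a sigma factor of the plastid RNA polymerase, rose 79.1-fold, and PRR9 (AT2G46790), a clock pseudo-response regulator, rose 73.8-fold. HY5 (AT5G11260), a transcription factor of the light response, rose 6.59-fold, from 26.8 ± 1.36 to 177 ± 10.4 CPM (counts scaled to library size, SD, n = 2). PIL1 (AT2G46970), a bHLH factor of the shade response, was 9.87-fold lower at 1 h, with a log2 change of -3.30 (SE 0.21, adjusted p = 1.63e-07).

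Of the 40 light signalling regulators measured, 24 rose and 7 fell in blue light at 1 h, the same counts as when adjusted over the list alone. The competitive list test, camera, gave this list an adjusted p of 8.76e-30, and an adjusted p = 0.00301 with an estimated correlation. SPA1, a partner of COP1, rose by a log2 change of 3.18, and BBX24, a B-box factor, by 3.01, while the homeobox gene HB-2 changed by -2.27. Of 23 clock genes, 13 rose and 0 fell (16 and 0 adjusted over the list alone), at an adjusted p of 5.46e-30 by camera and an adjusted p = 0.00499 with an estimated correlation. Among them ELF4 rose by 3.46, PRR5 by 2.55 and GI by 2.19 on the log2 scale. Of 23 flavonoid genes, 8 rose (11 adjusted over the list alone), among them the glycosyltransferase UGT78D2 by 4.47 and the regulator MYB12 by 3.56. Camera gave the flavonoid list 6.77e-13, against an adjusted p = 0.14 with an estimated correlation. Chalcone synthase, CHS, did not pass, with a log2 change of 1.63 (SE 0.76, adjusted p = 0.264). Of 30 auxin response genes, 9 fell and 1 rose (11 and 1 adjusted over the list alone). IAA29 changed by -3.25 and IAA19 by -2.27, and SAUR14 was the member that rose, by 2.45. Camera gave the auxin list 7.32e-08, against an adjusted p = 0.431 with an estimated correlation.

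Photosynthesis genes had begun to move at 1 h of blue light. Of 43 photosystem and light-harvesting genes, 7 rose and 0 fell (8 and 0 adjusted over the list alone), by camera at 2.24e-06, against an adjusted p = 0.61 with an estimated correlation. LHCB2.1 rose by 2.63 and LHCB2.2 by 2.50 on the log2 scale, and counts of these near-identical copies are uncertain where reads could map to both. CAO, which makes chlorophyll b, rose by 1.77, and ZEP, a xanthophyll cycle epoxidase, by 1.59. ELIP1, which encodes an early light-induced chloroplast protein, rose 30.5-fold (log2 4.93, SE 0.64, adjusted p = 1.39e-04; 4.18 without blue 1 h replicate 1). PORA, the protochlorophyllide reductase of etiolated seedlings, had a log2 change of -0.62 and did not pass (adjusted p = 0.790). Of the 20 SR splicing factors, 1 rose and 0 fell. In all, edgeR called 1870 of 23011 genes, 1230 higher and 640 lower, with 4335 genes at an unadjusted p under 0.05. Without blue 1 h replicate 2 the balance was 1309 higher and 1344 lower, and without blue 1 h replicate 1 it was 896 and 408. The count was 1073 without blue 0 h replicate 1, 1140 without blue 0 h replicate 2, 849 without the blue libraries numbered 1, and 808 when only the libraries of these groups entered the fit.

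The first hour of red light was compared with the red series at 0 h in the same way. Most of the light signalling and clock genes measured rose in this comparison too. GA2OX1 rose 190-fold, with a log2 change of 7.57 (SE 0.29, adjusted p = 4.59e-09). Its level in darkness was near the floor, so the size of this fold rests on few counts. It was -2.78 and -3.11 log2 CPM at red 0 h, against -1.95 and -2.11 in red 6 h dark. At blue 0 h it was -1.51 and -2.14. HY5 rose 8.57-fold (log2 3.10, SE 0.24, adjusted p = 1.57e-06), from 18.8 ± 3.49 to 161 ± 8.05 CPM (SD, n = 2). PRR9 rose 45.6-fold, SIG5 38.6-fold and ELIP1 37.0-fold. PIL1 was 14.2-fold lower, with a log2 change of -3.83 (SE 0.21, adjusted p = 1.39e-07), and IAA29 changed by -2.92.

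Of the light signalling regulators, 24 rose and 5 fell in red light at 1 h (24 and 6 adjusted over the list alone), by camera at 4.73e-41 and at an adjusted p = 8.13e-04 with an estimated correlation. Of the clock genes, 14 rose and 0 fell (18 and 0 adjusted over the list alone), by camera at 6.34e-45 and also at an adjusted p = 8.13e-04 with an estimated correlation. ASG4, a homeodomain-like factor, rose by 5.24, PRR5 by 3.29 and RVE7 by 2.62 on the log2 scale. Of the flavonoid genes, 8 rose (9 adjusted over the list alone), UGT78D2 by 3.85 and MYB12 by 2.78 (3.43 without red 0 h replicate 2), with camera at 1.17e-12 and an adjusted p = 0.161 with an estimated correlation. Of the photosystem genes, 8 rose (23 adjusted over the list alone), with camera at 7.99e-19 and an adjusted p = 0.23 with an estimated correlation. Of the auxin response genes, 6 fell and 1 rose (9 and 4 adjusted over the list alone), with camera at 0.00768 and an adjusted p = 0.718 with an estimated correlation. Of 9 heat shock genes, 3 rose (6 adjusted over the list alone), HSP70 by 3.13 (2.37 without red 1 h replicate 2), with camera at 1.70e-06 and an adjusted p = 0.178 with an estimated correlation. The 9 heat shock genes summed to 1802 CPM in red 1 h replicate 2 and 746 in replicate 1, and to at most 207 in any dark library. EdgeR called 1060 genes, 855 higher and 205 lower, with 3348 at an unadjusted p under 0.05. Lower genes numbered 353 and 109 without red 0 h replicates 1 and 2, and 128 and 72 without red 1 h replicates 1 and 2. The count was 516 without red 1 h replicate 2, 588 without red 0 h replicate 2, and 464 when only the libraries of these groups entered the fit.

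The early responses to blue and red light overlapped. Of the genes called, 704 were higher in both colours, where independent lists would share 45.7, and 156 were lower in both, where 5.70 would be shared. No gene was called in opposite directions, and log2 changes correlated at r = 0.61 across the 23011 genes, which are not independent replicates. The test of the difference between the 1 h responses called 0 genes with edgeR, with 1415 at an unadjusted p under 0.05, and 17 with DESeq2. Without blue 1 h replicate 2 edgeR called 386, and r was 0.400 without blue 1 h replicate 1.

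**Figure D2:**
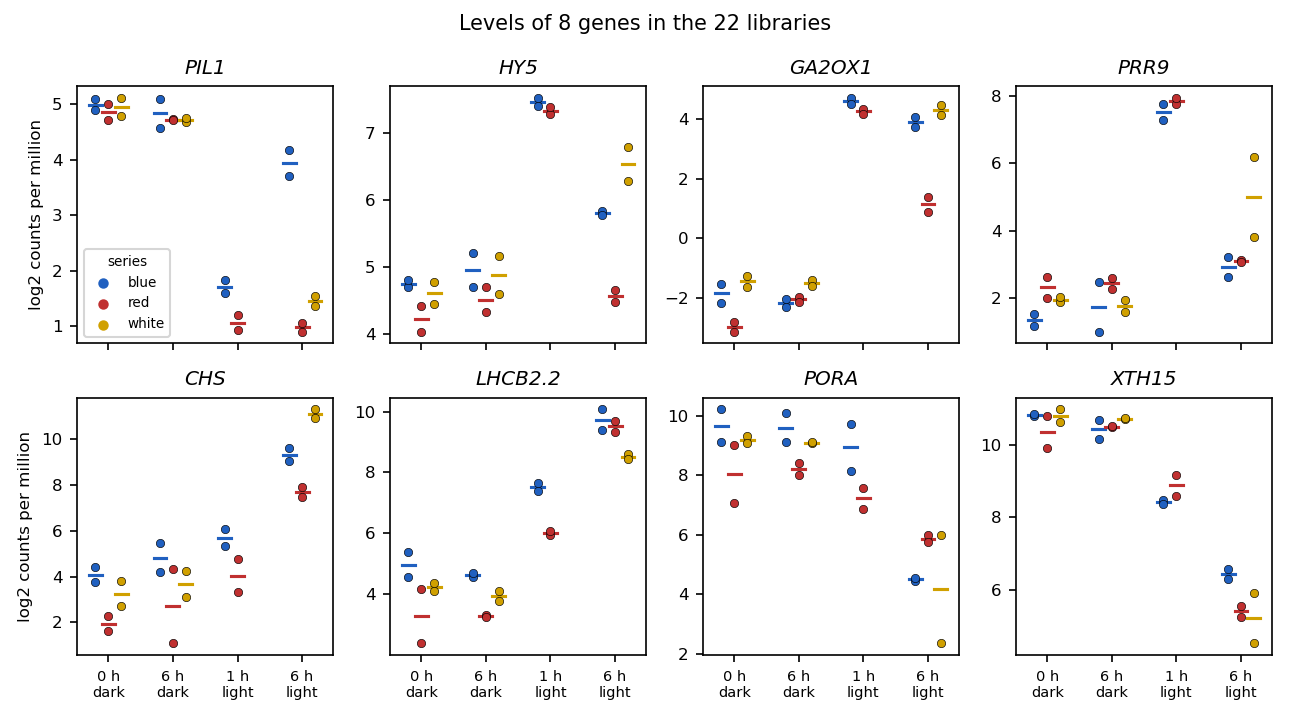
Log2 CPM of 8 genes, 1 point per library with short lines at group means, by time and light condition, coloured by series. PIL1 lies lower in light than in darkness, HY5 and PRR9 are highest at 1 h, and CHS and LHCB2.2 are highest at 6 h.

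After 6 h, light libraries of the 3 colours were compared with the 6 h dark libraries of the same series, giving the mean response to light. Most photosystem and flavonoid genes rose in each colour, and most auxin response and sugar starvation genes and 11 of 20 SR splicing factors fell in the mean. Dihydroflavonol reductase, DFR (AT5G42800), which makes anthocyanin precursors, rose 330-fold, a mean log2 change of 8.37 (SE 0.46, adjusted p = 2.67e-09; 10.76 without red 6 h dark replicate 2). LHCA1 (AT3G54890), an antenna protein of photosystem I, rose 42.8-fold (log2 5.42, SE 0.26, adjusted p = 8.27e-10). XTH15 (AT4G14130), a xyloglucan-modifying enzyme of the cell wall, was 28.4-fold lower (log2 -4.83, SE 0.24, adjusted p = 1.16e-09). GRF7 (AT5G53660), a growth-regulating factor, was 54.8-fold lower (log2 -5.78, SE 0.32, adjusted p = 2.59e-09).

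All 43 photosystem and light-harvesting genes rose at 6 h, also when adjusted over the list alone, by camera at 1.10e-35, against an adjusted p = 0.142 with an estimated correlation. PSAN rose by 3.68 and LHCB2.2 by 5.31 on the log2 scale. All 15 Calvin cycle genes rose, by camera at 2.31e-10, against an adjusted p = 0.224 with an estimated correlation, with CP12-2 at 3.45 and Rubisco activase, RCA, at 3.13. Of 28 chlorophyll and tetrapyrrole genes, 22 rose and 2 fell, the same counts adjusted over the list alone, by camera at 9.02e-12, against an adjusted p = 0.224 with an estimated correlation. CAO rose by 2.05 and HEMA1, the entry enzyme of the pathway, by 1.81. PORA changed by -3.84, a 14.3-fold lower level, and by -4.79 without white 6 h replicate 2. Of 15 carotenoid genes, 14 rose and 0 fell (the same adjusted over the list alone), with CYP97A3 at 3.36, by camera at 1.85e-10, against an adjusted p = 0.183 with an estimated correlation. Of 10 photorespiration genes, 9 rose (9 adjusted over the list alone), with SHM1 at 3.01, by camera at 3.21e-06, against an adjusted p = 0.224 with an estimated correlation.

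Of the 23 flavonoid genes, 22 rose and 1 fell at 6 h (the same adjusted over the list alone), by camera at 1.01e-20, against an adjusted p = 0.0859 with an estimated correlation. MYB12 rose by 6.63, CHS by 5.34 (6.13 without red 6 h dark replicate 2), CHIL by 4.57 and UGT78D2 by 4.19 on the log2 scale. Of the light signalling regulators, 28 rose and 9 fell (28 and 10 adjusted over the list alone), by camera at 5.50e-08, against an adjusted p = 0.118 with an estimated correlation. SIG5 rose by 4.21, BBX22 by 2.63 and SPA1 by 2.55, while PIL1 changed by -2.65 and HB-2 by -2.01. Of the clock genes, 11 rose and 6 fell (the same adjusted over the list alone), ELF4 rising by 4.41 and PRR5 by 1.91, with camera at 0.00836 and an adjusted p = 0.48 with an estimated correlation. Of 14 photoreceptor genes, 6 rose and 3 fell (the same adjusted over the list alone), and camera did not separate the list from other genes (adjusted p = 0.414). CRY3 rose by 2.76, and PHYA, the photoreceptor abundant in darkness, changed by -1.55. The photoreceptor list had a mean of 0.29, a median near 0 (-3.38e-03) and an upward direction by camera, and with library totals alone 5 rose and 7 fell.

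Auxin response genes mostly fell, 23 of 30, and 2 rose (the same adjusted over the list alone), by camera at 5.06e-05, against an adjusted p = 0.48 with an estimated correlation. IAA29 changed by -2.38, IAA19 by -1.95 and SAUR22 by -1.40, although SAUR22 has near-identical neighbours that make its counts uncertain, while SAUR14 rose by 3.21. Of 24 gibberellin and brassinosteroid genes, 13 fell and 5 rose (13 and 6 adjusted over the list alone), and camera did not separate the list (adjusted p = 0.414). That list had a median of -0.20 and a mean of 0.24, since GA2OX1 rose by 5.17 and GA3OX2, which makes active gibberellin, by 5.91 (7.14 without red 6 h dark replicate 2). Of 10 cell wall genes, 5 rose and 2 fell (the same adjusted over the list alone), EXPA1 rising by 2.68, with camera at an adjusted p of 0.749. Of 23 sugar starvation genes, 17 fell and 3 rose (the same adjusted over the list alone), by camera at 3.16e-05, against an adjusted p = 0.48 with an estimated correlation. BCAT2, which acts on branched-chain amino acids, changed by -3.49, SEN1 by -2.70 and the asparagine synthetase ASN1 by -2.47. Of 5 genes of seed reserve mobilisation, 4 fell (4 adjusted over the list alone), with isocitrate lyase, ICL, at -2.07 and PCK1 at -1.49, by camera at 5.39e-04, against an adjusted p = 0.0717 with an estimated correlation.

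The series concerns splicing, and gene totals of splicing factors were tested as lists. Of 20 SR splicing factors, 11 fell and 0 rose (the same adjusted over the list alone), by camera at 0.0125, against an adjusted p = 0.612 with an estimated correlation. SR34 changed by -0.98 (SE 0.11, adjusted p = 2.28e-06), RS40 by -0.85 (SE 0.05, adjusted p = 1.00e-08) and RS31 by -0.77 (SE 0.09, adjusted p = 4.99e-06). Of 16 other splicing and mRNA decay factors, 8 fell and 3 rose (the same adjusted over the list alone), with U2AF65A at -0.82, and camera gave 0.118. Of 16 DNA replication and cell division genes, 10 rose and 0 fell (the same adjusted over the list alone), with MCM5 at 0.74, and camera gave an adjusted p of 0.10. Of the heat shock genes, 8 rose (8 adjusted over the list alone), by camera at 0.0333, against an adjusted p = 0.48 with an estimated correlation. They summed to 1697 CPM in white 6 h replicate 2 and 671 in replicate 1. Of 21 touch, wounding and oxidative stress genes, 6 rose and 6 fell (the same adjusted over the list alone), with LOX2 rising by 3.88 and camera at 0.749. That list had a median of 0.01 and a mean of 0.11 against a downward direction by camera, and a median of -0.10 with library totals alone.

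Lists of markers of other material were tested in the same way. Of 15 root hair and endodermis markers, 9 rose and 1 fell (the same adjusted over the list alone), with CASP2 at 0.40 and camera at 0.414, and 5 rose and 1 fell with library totals alone. Of 3 guard cell markers, 2 fell (2 adjusted over the list alone), MYB60 by 0.75 and KAT1 by 0.64 on the log2 scale, and camera did not separate the list (adjusted p = 0.30). In white light alone 2 of the 3 fell (2 adjusted over the list alone), with camera at 0.0245 and an adjusted p = 0.27 with an estimated correlation, and the guard cell markers summed to 29.3 and 31.5 CPM in the dark libraries and 11.1 and 12.3 in the light libraries. Of the root markers 10 rose in white light (11 and 1 lower adjusted over the list alone), with camera at 0.0547. Of 12 seed storage markers, 1 fell (1 adjusted over the list alone), with camera at 0.414. Their summed level varied between libraries rather than groups, from 7.10 CPM to 858 in red 1 h replicate 2 and 608 in red 6 h dark replicate 2. Over all genes the mean contrast called 13441, of which 7475 were higher and 5966 lower, with 14381 at an unadjusted p under 0.05. With library totals alone the median of all genes shifted by -0.12 and the share of calls that were higher went from 55.6% to 41.0%.

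**Figure D3:**
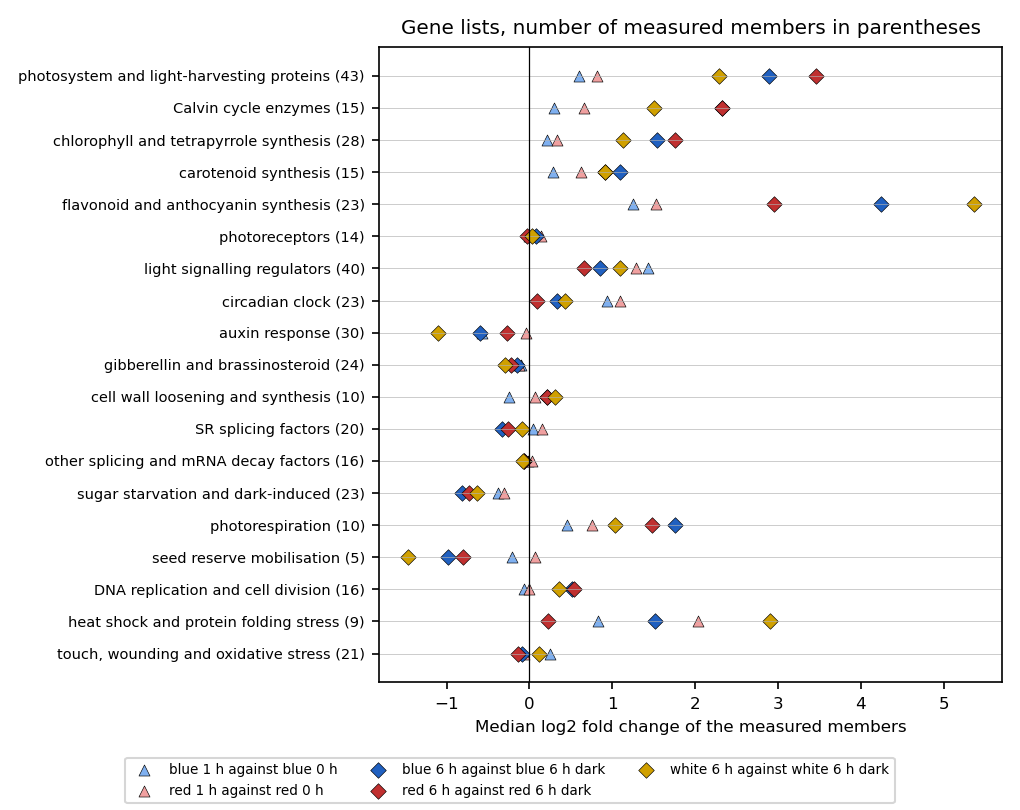
Median log2 fold change of the measured members of 19 gene lists, 1 symbol per light comparison, triangles for 1 h and diamonds for 6 h. Photosystem and flavonoid lists lie far to the right at 6 h, and the SR splicing factor list lies to the left of 0 at 6 h.

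Blue light at 6 h was compared with 6 h of darkness in the blue series. DFR rose by 279-fold (log2 8.12, SE 0.76, adjusted p = 2.43e-06; 7.42 without blue 6 h replicate 1) and LHCA1 by 38.8-fold (log2 5.28, SE 0.45, adjusted p = 1.22e-06). PORA was 36.2-fold lower, falling from 826 ± 379 to 22.8 ± 1.27 CPM (SD, n = 2). GRF7 changed by -5.75 (-5.08 without blue 6 h dark replicate 1) and XTH15 by -4.02 on the log2 scale. Of the photosystem genes 42 rose, of the Calvin cycle genes 15, of the carotenoid genes 14 and of the flavonoid genes 21, with 0 members lower in these lists and the same counts adjusted over the list alone. Among the Calvin cycle genes, the call of the Rubisco small subunit gene RBCS1A was lost with RLE factors (adjusted p = 0.0535). It was also lost with library totals alone (adjusted p = 0.0771) and when only these libraries entered the fit (adjusted p = 0.0778). With an estimated correlation the photosystem list had an adjusted p = 0.137 and the flavonoid list an adjusted p = 0.108. PIL1, which had been 9.87-fold lower at 1 h, was 1.88-fold lower at 6 h (log2 -0.91, SE 0.19, adjusted p = 0.00151), a call lost when only these libraries entered the fit (adjusted p = 0.0551). CHS rose by 4.40 (5.17 without blue 6 h dark replicate 2), lost without the blue libraries numbered 1 (adjusted p = 0.0506), and HY5 by 0.82, lost without blue 6 h dark replicate 1 (adjusted p = 0.0985). EdgeR called 8597 genes, 5243 higher and 3354 lower, with 10490 at an unadjusted p under 0.05. Lower genes numbered 2209 without blue 6 h replicate 1. The count was 4810 when only the libraries of these groups entered the fit, and with library totals alone the median shifted by -0.15 and the share higher went from 61.0% to 41.1%.

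Red light at 6 h was compared with 6 h of darkness in the red series. Antenna genes of the photosystems rose, and so did DFR, which had few counts in darkness (log2 7.50, SE 0.79, adjusted p = 1.08e-05; 6.48 and 14.68 without red 6 h dark replicates 1 and 2). LHCA1 rose 80.1-fold (log2 6.32, SE 0.48, adjusted p = 9.99e-07), LHCB2.2 by 6.24 and PSAH2 by 5.17 on the log2 scale. All 43 photosystem genes rose (43 adjusted over the list alone), against an adjusted p = 0.0782 with an estimated correlation, and 16 flavonoid genes rose (18 adjusted over the list alone), against an adjusted p = 0.125 with an estimated correlation. PIF7, a phytochrome-interacting factor, rose 22.6-fold (log2 4.50, SE 0.28, adjusted p = 3.40e-07), and PIL1 was 13.6-fold lower (log2 -3.76, SE 0.21, adjusted p = 2.36e-07). HY5 had a log2 change of 0.05 and did not pass (SE 0.22, adjusted p = 0.900), and PORA had -2.35 and did not pass (adjusted p = 0.0571). EdgeR called 6378 genes, 4055 higher and 2323 lower, with 8742 at an unadjusted p under 0.05. With library totals alone the share higher went from 63.6% to 51.4%. The count was 3938 without red 6 h replicate 2, 3957 without red 6 h dark replicate 2 and 4082 without red 6 h dark replicate 1.

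White light at 6 h was compared with 6 h of darkness in the white series. DFR rose by 717-fold (log2 9.49, SE 0.86, adjusted p = 1.66e-06; 10.11 without white 6 h dark replicate 2), MYB12 by 373-fold (log2 8.54, SE 0.42, adjusted p = 6.43e-09) and CHS by 164-fold (log2 7.36, SE 0.96, adjusted p = 3.89e-05; 8.04 without white 6 h dark replicate 2). LHCA1 rose by 4.66 and PSAN by 3.15. HY5 rose by 1.65 (SE 0.22, adjusted p = 5.06e-05), and PIL1 was 9.66-fold lower (log2 -3.27, SE 0.21, adjusted p = 5.89e-08). Counts were the same adjusted over the list alone for the lists that follow. Of the flavonoid genes 22 rose, against an adjusted p = 0.0636 with an estimated correlation, and of the photosystem genes 39 rose, against an adjusted p = 0.297 with an estimated correlation. Of the auxin genes 22 fell and 1 rose, against an adjusted p = 0.319 with an estimated correlation. All 9 heat shock genes rose, HSP70 by 3.84 and HSFA2 by 4.04 (3.06 and 2.19 without white 6 h replicate 2), against an adjusted p = 0.297 with an estimated correlation. CCA1, a morning clock gene, had a log2 change of 0.43 and did not pass (adjusted p = 0.505), and without white 6 h replicate 2 its change was -1.32. In other comparisons CCA1 was called higher at 1 h in blue (2.43 without blue 0 h replicate 1) and red light (2.29 without red 1 h replicate 2). It was called lower at 6 h in red light (-1.42 without red 6 h dark replicate 1) and in the mean (-0.70 without blue 6 h dark replicate 2). Each of these calls was lost without the library given. EdgeR called 9573 genes, 5348 higher and 4225 lower (2591 lower without white 6 h replicate 1), with 11396 at an unadjusted p under 0.05. With library totals alone the median shifted by -0.12 and the share higher went from 55.9% to 40.7%.

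**Figure D4:**
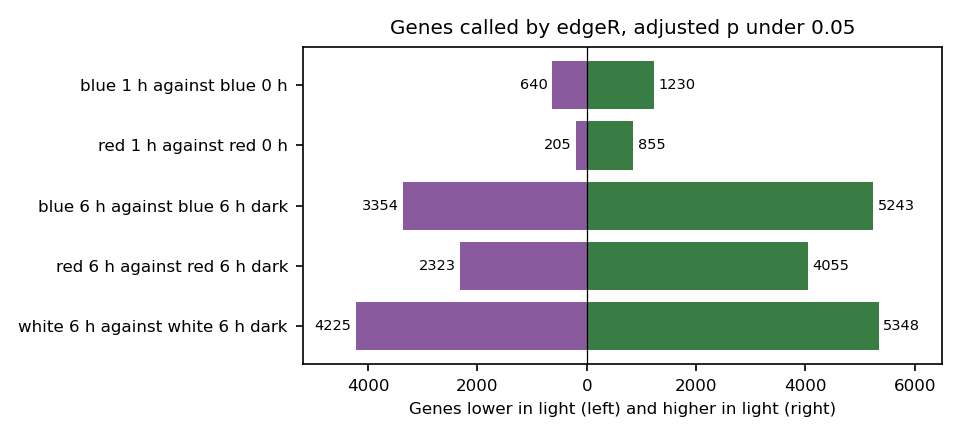
Number of genes called by edgeR in each comparison of light with darkness, bars to the right for genes higher in light and to the left for genes lower in light. The comparisons at 6 h (6378 to 9573 genes) have more calls than those at 1 h (1060 and 1870 genes).

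The responses to the 3 colours at 6 h were then set against each other. Blue and red shared 3543 higher genes, where independent lists would share 924, and 1915 lower genes, where 339 would be shared, with 4 in opposite directions (r = 0.82 across genes). Blue and white shared 4046 higher genes (1219 for independent lists) and 2689 lower genes (616), with 2 opposite (r = 0.84). Red and white shared 3035 higher genes (942 for independent lists) and 1837 lower genes (427), with 27 opposite (r = 0.73). Each colour has its own dark libraries, so no control was shared.

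PIL1 set blue light apart from the other colours. Its response was higher by 2.85 in blue than in red light (SE 0.28, adjusted p = 5.78e-04) and by 2.36 in blue than in white light (SE 0.27, adjusted p = 0.00506). Both calls were lost when only the libraries of the contrast entered the fit (adjusted p = 0.205 and 0.255). AT1G13670, an uncharacterised gene, responded 1.79 higher in blue than in red light (SE 0.20, adjusted p = 0.00129). COX15, an assembly factor of cytochrome oxidase, responded lower in blue than in white light, with a difference of -1.31 (SE 0.14, adjusted p = 0.00506). These calls too were lost in the fit of the contrast's libraries alone (adjusted p = 0.445 and 0.226). Between blue and red light edgeR called 22 genes, 21 higher in blue and 1 lower, and 72 with the replicate number as a block, with 1460 at an unadjusted p under 0.05 and 133 with DESeq2. Between blue and white light it called 14 genes, 4 higher in blue and 10 lower, and 28 with the block, with 1880 at an unadjusted p under 0.05 and 177 with DESeq2. In the fit of the contrast's libraries alone both counts were 0.

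These counts changed when single libraries were left out. Each such fit leaves a group with 1 library, so a loss of replication cannot be told from dependence on 1 library. The blue against red count of 22 was 4 without blue 6 h dark replicate 1, 7 without blue 6 h replicate 1, 47 without blue 6 h replicate 2, 8 and 5 without red 6 h dark replicates 1 and 2, and 7 and 13 without red 6 h replicates 1 and 2. The blue against white count of 14 was 2 without blue 6 h dark replicate 2, 2 without blue 6 h replicate 2, 2 and 3 without white 6 h dark replicates 1 and 2, and 8 without white 6 h replicate 2.

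Red and white light differed in more genes, and flavonoid and auxin genes were among them. Flavonoid genes responded less in red than in white light, with 7 of 23 lower in red and 0 higher (11 and 0 adjusted over the list alone) and a median difference of -1.54. Camera gave 7.90e-15, against an adjusted p = 0.0924 with an estimated correlation. Of the light signalling regulators 9 of 40 were lower and 0 higher (15 and 6 adjusted over the list alone), by camera at 1.14e-07, against an adjusted p = 0.104 with an estimated correlation. Of the auxin genes 4 of 30 were higher and 0 lower (13 and 0 adjusted over the list alone), by camera at 1.97e-10, against an adjusted p = 0.333 with an estimated correlation. No photosystem gene passed over all genes. Adjusted over the list alone, 34 of 43 were higher in red and 1 lower, with a median difference of 1.38. Camera gave 4.58e-16, against an adjusted p = 0.333 with an estimated correlation. Part of this difference lay in the dark libraries. The list's median log2 CPM was 5.83 and 6.01 in red 6 h dark, against 6.34 and 6.66 in white 6 h dark. In 6 h light it was 9.38 and 9.95 in red, against 9.06 and 8.87 in white. RTFL21 (AT1G67265), of the ROTUNDIFOLIA-like small peptides, was 3.08 higher in red (SE 0.34, adjusted p = 2.69e-04), and MIR167d (AT1G31173), a microRNA precursor, 2.73 higher (SE 0.44, adjusted p = 0.00334). AT3G57020, annotated as a phosphotriesterase-like protein, had a difference of -4.44 (SE 0.52, adjusted p = 3.75e-04; -5.11 without red 6 h replicate 1).

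In all 627 genes differed between red and white light, 200 higher in red and 427 lower, with 3922 at an unadjusted p under 0.05. DESeq2 called 1335 and the fit with the replicate block 1449. With library totals alone the share higher in red went from 31.9% to 45.7%. The count was 283 and 326 without red 6 h dark replicates 1 and 2, 292 without red 6 h replicate 2, 276 and 294 without white 6 h dark replicates 1 and 2, and 412 without white 6 h replicate 1, and lower genes numbered 282 without white 6 h replicate 2.

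The response at 6 h was compared with the response at 1 h within each colour. In blue and red light 11 and 10 of 23 clock genes responded less at 6 h, and 36 and 33 of 43 photosystem genes more. PRR9 differed by -5.20 in blue (SE 0.85, adjusted p = 0.00158; -4.24 without blue 6 h dark replicate 2) and by -4.85 in red light (SE 0.82, adjusted p = 0.00307). The B-box gene bbx23 (AT4G10240) differed by -5.59 in blue (adjusted p = 0.00267) and -5.54 in red light (adjusted p = 0.00559). Its difference was -4.98, -6.28 and -4.78 without blue 6 h dark replicate 1 and blue 6 h replicates 1 and 2, and -6.28, -7.81 and -4.71 without red 0 h replicate 1 and red 6 h replicates 1 and 2. In blue light 36 of 43 photosystem genes responded more at 6 h (39 adjusted over the list alone), with a median difference of 2.18, by camera at 3.32e-28, against an adjusted p = 0.241 with an estimated correlation. Of 23 clock genes 11 responded lower and 1 higher (14 and 2 adjusted over the list alone), with a median difference of -0.64, by camera at 7.92e-08, against an adjusted p = 0.241 with an estimated correlation. In red light the adjusted p = 0.112 for the photosystem and 0.0817 for the clock list with an estimated correlation (43 higher, and 14 lower and 1 higher, adjusted over each list alone). The anthocyanin acyltransferase AT5MAT had a difference of 5.84 in blue (SE 0.75, adjusted p = 5.88e-04; 5.19 without blue 6 h replicate 1). In red light LHCB1.2 had a difference of 5.85 (SE 1.13, adjusted p = 0.00586; 4.24 and 6.60 without red 0 h replicates 1 and 2), with copies nearly identical to it that make its counts uncertain, and ASG4 one of -5.08 (SE 0.78, adjusted p = 0.00211).

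Of the 1230 genes higher at 1 h of blue light, 835 were also higher at 6 h, where independent lists would share 280, and 33 were lower. Of the 855 genes higher at 1 h of red light, 532 were also higher at 6 h (151 for independent lists) and 19 were lower. The difference between times was called in 3553 genes in blue, 2105 higher at 6 h and 1448 lower, with 6704 at an unadjusted p under 0.05, and in 2370 genes in red, 1340 higher and 1030 lower, with 5693 at an unadjusted p under 0.05. With library totals alone the blue median shifted by -0.11 and the share higher went from 59.2% to 42.4%. Lower genes in blue numbered 943 without blue 6 h replicate 1. The blue count was 1785 without blue 0 h replicate 1, 1887 without blue 6 h dark replicate 2, 1021 without the blue libraries numbered 1, and 1524 in the fit of the contrast's libraries alone. The red count was 1545 without red 0 h replicate 1, 1283 and 1197 without red 6 h dark replicates 1 and 2, 1266 and 1264 without red 1 h replicates 1 and 2, 1197 without red 6 h replicate 2, and 1525 in the fit of the contrast's libraries alone.

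Darkness alone was tested by comparing 6 h dark with 0 h over the 3 series. HY5 had a log2 change of 0.27 (SE 0.13), CHS 0.92 (SE 0.44), PIL1 -0.18 (SE 0.11) and PORA -0.10 (SE 0.47), all at an adjusted p of 1.00. EdgeR called 0 genes, with 769 at an unadjusted p under 0.05 where chance gives 1151, and DESeq2 called 0. No member of any of the 22 lists was called. The 0 h libraries of the 3 series were also compared with each other. EdgeR called 0 genes, with 2206 at an unadjusted p under 0.05, DESeq2 called 79 and the fit with the replicate block 187. Without red 0 h replicate 1 edgeR called 437.

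Plastid and mitochondrial genes held 0.127% of counts in the 6 h light libraries (SD 0.0503, n = 6) and 0.184% in the 6 h dark libraries (SD 0.0434, n = 6). The difference of -0.0564 percentage points had an exact permutation p of 0.0833, two-sided, over 216 arrangements of labels within series. With 1 library left out at a time, the difference ran from -0.0697 without blue 6 h replicate 1 to -0.0393 without blue 6 h dark replicate 1. The result was the same in 11 of 12 such runs, and the test passed only without blue 6 h replicate 1.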

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

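The tests of library depth and pool size, of levels in darkness, and of white light replicate 2 were chosen after the results were seen, and so was the direct comparison of 6 h with 1 h of light. The genes, counts and lists at the end are given because a test of the difference between 2 responses passed, by edgeR for genes and by camera at the preset correlation for lists with at least 4 members called in the same direction, a limit chosen after the results were seen. Genes are given where the call held without each library in turn, which was so for 2 of 5, 2 of 9, 3 of 10, 5 of 10 and 7 of 10 genes in the 5 comparisons, in the order below.

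The light and dark libraries at 6 h differed in 13441 genes, and dark libraries had fewer counts and shared pools 4 at a time. After thinning to the smallest total, 12599 of those genes were called again, which argues against depth as the cause. Of 100 splits of the 12 libraries, out of 462 possible, 1 gave as many genes. It was the real one, with 13209 against 4697 for the highest other. Of 12 splits parting all pairs the highest other gave 0. The other splits mix light and dark libraries on a side, so a light effect adds to their spread and lowers their counts. A share of 1 in 100 is also the smallest this test can give, so it does not exclude chance. If pool size were the whole cause, 1 h and 6 h of light would differ alike from darkness. The slope of 1 h on 6 h changes was at most 0.328 over the genes called in the mean at 6 h, a choice that itself lowers the slope. The direct comparison of 6 h with 1 h of light, both in pools of 2, does not rest on that choice. It gave 7536 genes in blue and 6402 in red, which argues against pool size as the whole cause. A smaller part of the differences could still come from pool size, which the design does not separate from light, and the response to light itself remains the main biological explanation.

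For 6 h dark against 0 h the real split gave 0 genes, so all 100 splits gave as many by construction and the number of splits says nothing about chance. The highest other split gave 646 genes, which points to a structure of the samples. That split had 5 of 6 libraries on one side numbered 1, and other splits of that kind gave between 0 and 465 genes.

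The responses to red and white light at 6 h differed in 627 genes. The 427 genes lower in red had median changes of 0.20 in red, 1.35 in white and 0.72 in blue light, and the 200 higher in red had 0.04, -1.10 and -0.53. For the 627 genes, levels in darkness that already differed between the series are argued against. Their 0 h difference had a slope of 0.0278 on the difference in response. No photosystem gene is among the 627, so this does not cover that list. A biological explanation, the blue part of white light, stays open. The slope of blue minus red on white minus red was 0.493 from the edgeR changes and 0.512 on log2 CPM (jackknife SE 0.107 for the latter). Both sides share the red libraries and the genes were chosen for their difference between red and white, so the slope decides nothing.

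White light 6 h replicate 2 stood apart from replicate 1 in genes of the early response. In 236 genes that rise early and pass, replicate 2 lay 0.40 above replicate 1 on the log2 scale, where the other 10 groups had -0.05 to 0.23. A shorter light exposure may account for this, and the 479 genes that fall late lay 0.25 higher, outside -0.05 to 0.16 in the other groups, but the 874 genes that rise late lay at -0.14, within -0.24 to 0.32. Heat or handling stress may account for it too. The heat shock genes lay 1.24 higher, where red 1 h reached 1.25 with a difference of 0.05 in the early genes, which goes against it. Blue 0 h also goes against it, with 0.53 and -0.03, while blue 6 h dark, with 0.85 and 0.23, goes with it. The early genes were chosen as called in blue and red light at 1 h, which favours a small difference between the red 1 h replicates. The explanations cannot be told apart. Seed storage markers differed as well, summing to 253 CPM in replicate 2 and 39.3 in replicate 1. In red 1 h replicates 2 and 1 they summed to 858 and 34.4 CPM. Whether this bears on the early genes was not tested. No biological explanation was tested, since the design gives both libraries the same treatment.

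PIL1 responded 2.85 higher in blue than in red light at 6 h, and AT1G13670 1.79 higher. Against white light, PIL1 responded 2.36 higher in blue and COX15 lower, with a difference of -1.31. In all, 22 genes differed between blue and red light and 14 between blue and white light. In red against white light RTFL21 differed by 3.08, MIR167d by 2.73 and AT3G57020 by -4.44. List medians in that contrast were -1.54 for flavonoid genes, -0.54 for light signalling regulators and 0.83 for auxin genes, and none of these lists passed with an estimated correlation (adjusted p = 0.0924, 0.104 and 0.333).

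Between 6 h and 1 h, 3553 genes responded differently in blue light and 2370 in red light. In blue light the genes AT5MAT (5.84) and AT4G28780 (5.79) responded higher at 6 h, and bbx23 (-5.59), PRR9 (-5.20) and AT3G12320 (-4.96) lower. In red light LHCB1.2 (5.85), AT3G06880 (5.36) and AT2G32550 (5.06) responded higher, and bbx23 (-5.54), ASG4 (-5.08), PRR9 (-4.85) and CYP96A5 (-4.77) lower. The list medians in blue light were 2.18 for photosystem, 1.97 for Calvin cycle, 0.87 for chlorophyll, 0.73 for carotenoid, 1.45 for flavonoid, 1.43 for photorespiration, -0.64 for clock and -0.44 for SR splicing factor genes. None passed with an estimated correlation (adjusted p = 0.241 for photosystem, Calvin cycle, flavonoid, photorespiration and clock, 0.398 for chlorophyll, 0.333 for carotenoid and 0.493 for SR genes). In red light they were 2.58 for photosystem, 1.5 for Calvin cycle, 1.01 for chlorophyll, 0.57 for carotenoid, 1.07 for flavonoid, -0.68 for light signalling, -0.62 for clock and -0.43 for SR splicing factor genes. None passed with an estimated correlation (adjusted p = 0.112 for photosystem, 0.114 for light signalling, 0.0817 for clock, 0.35 for chlorophyll and 0.352 for the other lists).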

How the results depend on the processing

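Thinning, leaving out the blue libraries numbered 1, and the direct comparison of 6 h with 1 h of light were tests chosen after the data were seen. All 14 counts of genes stayed within 1.5 times of their values with RLE factors, library totals alone, no filter, the stricter filter, no organelle genes, and thinning. Counts of named genes here cover every gene that the rules gave, also those the text does not name. Of 464 calls of named genes, 463 were kept with RLE factors, 458 with library totals alone, 464 with DESeq2, 455 after thinning, 463 with the replicate block and 408 in fits of the contrast's libraries alone. Leaving out 1 library kept 2451 of 2696 such calls. Among 286 list tests, called or not, 150 calls were lost with an estimated correlation and 73 with fry, which gained 14. The 136 tests that an estimated correlation left unchanged include those called in neither setting, so 150 of 286 is not the share of calls lost. The change of CCA1 in white light, 0.43 and not called, was reversed without white 6 h replicate 2, at -1.32, and was 1.2 without white 6 h replicate 1. Thinning to the smallest total gave 12871 genes for the mean at 6 h against 13441. In simulated counts with 2 libraries per group, 13.4% of 1.5-fold and 78.8% of 4-fold changes were recovered for blue light at 1 h.

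A log2 change of at least 1, which by its construction calls fewer genes, left 854 genes for blue and 607 for red light at 1 h, 2941 for blue, 2246 for red and 3482 for white light at 6 h, 3066 for the mean, 348 for red against white light, and 1693 and 1239 for 6 h against 1 h in blue and red light. DESeq2 called 17 genes for blue against red light at 1 h, 133 at 6 h, 177 for blue against white, 1335 for red against white and 79 between the 0 h libraries, and the cause was not tested. In the simulated counts it gave 21, 37 and 27 false calls for blue light at 1 h, the mean at 6 h and red against white light. EdgeR gave 5, 5 and 4 there, so the larger DESeq2 counts may hold more false calls. DESeq2 also recovered more of the 2-fold changes between red and white light, 52.3% against 28.8%. Leaving out the blue libraries numbered 1 gave 849 genes for blue light at 1 h, 5 for blue against red at 6 h and 1021 for 6 h against 1 h in blue. Fits of the contrast's libraries alone, with fewer libraries to estimate the spread, gave 808 and 464 at 1 h in blue and red, 4810 for blue at 6 h, 0 for blue against red and 0 for blue against white at 6 h, and 1524 and 1525 for 6 h against 1 h in blue and red. Compared directly, without dark libraries, 6 h and 1 h of light differed in 7536 genes in blue and 6402 in red.

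With the replicate block, counts were 72 for blue against red and 28 for blue against white light at 6 h, 1449 for red against white, 3578 for 6 h against 1 h in red and 187 between the 0 h libraries. The block moved no other count by over 1.5 times, lost 1 call of a named gene and 2 list calls, and gained 6 calls among the 35 named results not called and 7 list calls.

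With 1 library left out at a time, counts ran from 1073 to 2653 for blue and 516 to 1422 for red light at 1 h, 3938 to 5351 for red light at 6 h, 0 to 386 for blue against red at 1 h, 4 to 47 at 6 h, 2 to 21 for blue against white, 276 to 523 for red against white, 1785 to 3614 and 1197 to 2279 for 6 h against 1 h in blue and red, and 0 to 437 between the 0 h libraries. Counts for blue light at 6 h (6007 to 6958), white light (6405 to 7986) and the mean (12347 to 12960) stayed within 1.5 times. The organelle share differed by -0.0697 to -0.0393 percentage points. Its test gave the same result in 11 of 12 runs and passed only without blue 6 h replicate 1. The correlation of blue and red responses at 1 h ran from 0.400 to 0.640, at 6 h from 0.750 to 0.801, and that of blue and white from 0.780 to 0.821. With the stricter filter, which removes weakly expressed genes, these were 0.793, 0.915 and 0.908.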

Other observations

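Other gene groups at 6 h are given by colour, with no test of the difference between colours. Of 23 sugar starvation genes, 16 fell and 2 rose in blue, 13 fell and 0 rose in red, and 11 fell and 3 rose in white light, against an adjusted p = 0.544, 0.418 and 0.607 with an estimated correlation. Of 20 SR splicing factors, 7 fell in blue, 5 in red and 5 in white light, where 1 rose, against an adjusted p = 0.544, 0.667 and 0.764 with an estimated correlation. In blue light the call of SR30 was lost without each light or dark library at 6 h in turn. In white light the call of SR45a, a rise, was lost without white 6 h replicate 2. Of the calls in red light those of RS31, SCL30 and SR34 were lost without red 6 h replicate 1 (adjusted p = 0.0869, 0.0534 and 0.0561), that of SR34 also without red 6 h dark replicate 2 (adjusted p = 0.0502), and that of RS31 also without each other red library at 6 h (adjusted p = 0.0623 to 0.0694). PHYA changed by -1.14, -1.65 and -1.85 on the log2 scale in blue, red and white light. The isocitrate lyase ICL changed by -2.27, -1.88 and -2.07, and PCK1 by -1.50, -1.35 and -1.61. Of 16 DNA replication genes, 8 rose in blue, 9 in red and 0 in white light and 0 fell, against an adjusted p = 0.718, 0.695 and 0.92 with an estimated correlation. MCM5 rose by 0.96 in red light and by 0.79 in blue light, the latter lost without blue 6 h dark replicate 2 (adjusted p = 0.0634) or blue 6 h replicate 1 (adjusted p = 0.0713).

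Of 9 heat shock genes, 2 responded lower in red than in white light at 6 h and 0 higher (8 and 0 adjusted over the list alone), with a median difference of -2.56, by camera at 2.95e-09, against an adjusted p = 0.0924 with an estimated correlation. Their sum was 1697 CPM in white 6 h replicate 2, which stands apart from replicate 1 at 671, and 260 and 284 in the red 6 h libraries.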
